A study of Rattus norvegicus with 6 samples.

How the data were processed

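Gene expression was measured in rat aortic smooth muscle cells of passage 3 to 5 on Affymetrix rat arrays, in 3 static cultures and 3 cultures exposed to fluid shear stress of 14 dyn per square centimetre for 24 h. Per the labels, cells were first held for 24 h in medium with 0.1% albumin in place of 10% serum, and sheared cells lay in a parallel-plate chamber fed by a height difference between reservoirs. Each static sample carried the same pairing number as 1 sheared sample, and the series design calls the experiment paired. What a pair shared (animal, culture or day) is not stated, so p-values measure the spread between these samples, which may be technical.

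Per the submitters' processing notes, the authors used MAS5 to make the deposited intensity values; its version is not given in the sources used here. The deposited intensity was on a linear scale with 1 value per probe set, and no detection calls were used here. Its mean over all probe sets without the highest and lowest 2% was 100.0 on each array, so arrays were already scaled to each other. The number of arrays limits the precision, and low signals could not be told from background.

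The table held 31099 probe sets, of which 57 were Affymetrix controls. Of the other 31042, the platform annotation given for the probes paired 20826 with 1 gene symbol, 436 with several and 9780 with none. Genes were named only from probe sets with 1 symbol; a gene table of assembly GRCr8 matched 20758 of these by gene identifier and changed 0 symbols. No coordinates are given, since no build is named for the arrays. Where a gene had several probe sets, the one with the highest mean over the 6 arrays stood for it.

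The values held exact zeros, 3 to 10 per array, so 16 was added before log2, as planned for that case. Fold changes are therefore on the log2(signal + 16) scale, which understates the change of dim genes. The 30% of probe sets with the lowest mean were left out, which set a limit of 4.50 on the log2 scale and left 21729 probe sets. Shear was compared with static in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend, and with the pairing number as a fixed block. P-values were two-sided and adjusted by Benjamini-Hochberg over all probe sets tested, with a threshold of 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

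The pairing was taken from the labels. Deviations from the group means correlated by 0.071, 0.065 and 0.063 within pairs 1, 2 and 3, and each array correlated best with its own partner.

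The 21 gene lists were fixed before the data were examined: contractile smooth muscle, coagulation and fibrinolysis, extracellular matrix, matrix proteases and inhibitors, cell cycle, apoptosis, cholesterol synthesis, oxidative stress (NRF2), vasoactive mediators, inflammation, growth factors, flow-responsive and immediate early genes, YAP and SRF targets, hypoxia and glycolysis, ER stress and amino acid response, heat shock, interferon, circadian, and endothelial, fibroblast and leukocyte markers. Of their 602 entries 559 were matched to a probe set, 3 through a synonym, and 495 were tested. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Control transcripts were compared by exact permutation tests, two-sided, for which 0.1 is the smallest possible p.

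The rule for named genes, also fixed beforehand, took Tfpi2 and Tfpi, the 12 risen and 12 fallen genes with the largest change that passed and had the same sign in all 3 pairs, and up to 4 members of each list by smallest p. It gave 100 probe sets beside Tfpi2. A further 94 probe sets were looked at by name after results had been seen, some of them because their calls differed between settings, and the stability of both sets is counted separately in the closing section.

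Alternatives chosen before the data were examined were no replicate block, a random block, quantile normalization, median centring, no filter, a 50% filter, a pseudocount of 64, eBayes without trend or with robust estimation, each pair left out in turn, a threshold of 0.1, camera with an estimated correlation, fry, and the mean over a gene's probe sets. The planned pseudocount of 16 became the setting used. A pseudocount of 1 was added after seeing the data. Fits with a pair left out kept the block and rested on 2 pairs, with 1 residual degree of freedom. Calls gained or lost in them therefore lean on the variance that eBayes borrows from other probe sets. The fit was tested on simulated arrays in which 200 of 21729 probe sets were changed: 1.52% were called at a log2 change of 0.5, 34.3% at 1 and 82.1% at 2, and 1.25% of calls were false. In the data 52.8% of probe sets were called. The Benjamini-Hochberg threshold depends on the share changed, so these rates do not describe the fit reported here.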

Results

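Expression was profiled in 6 cultures of rat aortic smooth muscle cells, 3 kept static and 3 under laminar fluid shear stress at an arterial level, paired 1 to 3. The comparison addresses which transcripts differ under shear stress in this cell type, and the series title names Tfpi2. Any other difference between the chamber and static cultures goes with the groups. Median signal per array was 21.1, 22.6 and 21.4 in static arrays 1 to 3 and 18.9, 17.8 and 17.3 in shear arrays 1 to 3. Correlations across probe sets were 0.987 to 0.991 among static arrays, 0.980 to 0.993 among shear arrays and 0.882 to 0.906 between the groups. The first principal component held 85.8% of the variance and separated the groups; the second held 6.28% and set shear array 1 apart from shear arrays 2 and 3.

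Tfpi2, which encodes a Kunitz-type serine protease inhibitor of the extracellular matrix, rose more than any other named gene on the log2(signal + 16) scale. Its signal was 40.0 ± 24.0 (SD, n = 3) in static cells and 4396 ± 696 (SD, n = 3) in sheared cells, a ratio of 110. Linear ratios of Dusp2 (127) and Mmp3 (113) were higher, from static signals near the floor. The log2 fold change was 6.37 (95% interval 5.79 to 6.94, adjusted p = 2.4e-06), with 5.46, 6.87 and 6.78 in pairs 1 to 3. Tfpi, the related inhibitor of tissue factor, fell on both of its probe sets, by 0.76 and by 0.91 on the log2 scale.

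Between sheared and static cells 11471 of 21729 probe sets (52.8%) changed, of which 5283 rose and 6188 fell. At least 2-fold changes were seen in 1296 risen and 1944 fallen probe sets. Those counts moved with the pseudocount (680 and 953 at 64, 2039 and 3198 at 1). By gene, 3131 of 11248 rose and 3385 fell, and 181 genes had probe sets changed in both directions. Risen probe sets made up 46.1% of the calls, but 52.4% after quantile normalization and 59.1% after median centring. The median log2 fold change of all tested probe sets was -0.067, and 0.021 and 0.082 under those scalings, so the direction of changes of that size depends on the scaling.

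After Tfpi2, the genes that rose most were Ccl2, a monocyte chemokine (5.32 on the log2 scale), the MAP kinase phosphatases Dusp2 (5.23) and Dusp5 (4.95), the stromelysin Mmp3 (4.68), the cystine transporter Slc7a11 (4.65) and Zfand2a (4.61). Plaur, the urokinase receptor, rose by 4.27 and its ligand Plau by 3.86, with Nabp1 (4.24), Hopx (4.09) and Chst1 (3.83) between or beside them. A second Plaur probe set rose less, by 0.99. Static signals of Dusp2 (7.17 ± 2.96), Mmp3 (5.67 ± 0.907) and Plau (9.73 ± 2.14) were low, so their folds depend on the pseudocount. The genes that fell most were Ankrd1 (-4.12), Pclaf (-4.10), Kif20a (-4.09), Vsnl1 (-3.89), Arsi (-3.88), Ect2 (-3.88), Tnfrsf11b (-3.79), Fos (-3.76), Mki67 (-3.71), Cdca3 (-3.69), Racgap1 (-3.67) and Ccnb2 (-3.61). A second Fos probe set did not pass (-0.06). Sheared signals of Ankrd1 (9.33) and Vsnl1 (11.4 ± 10.4) were low, so the folds and order of the fallen genes depend on the pseudocount too.

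**Figure D1:**
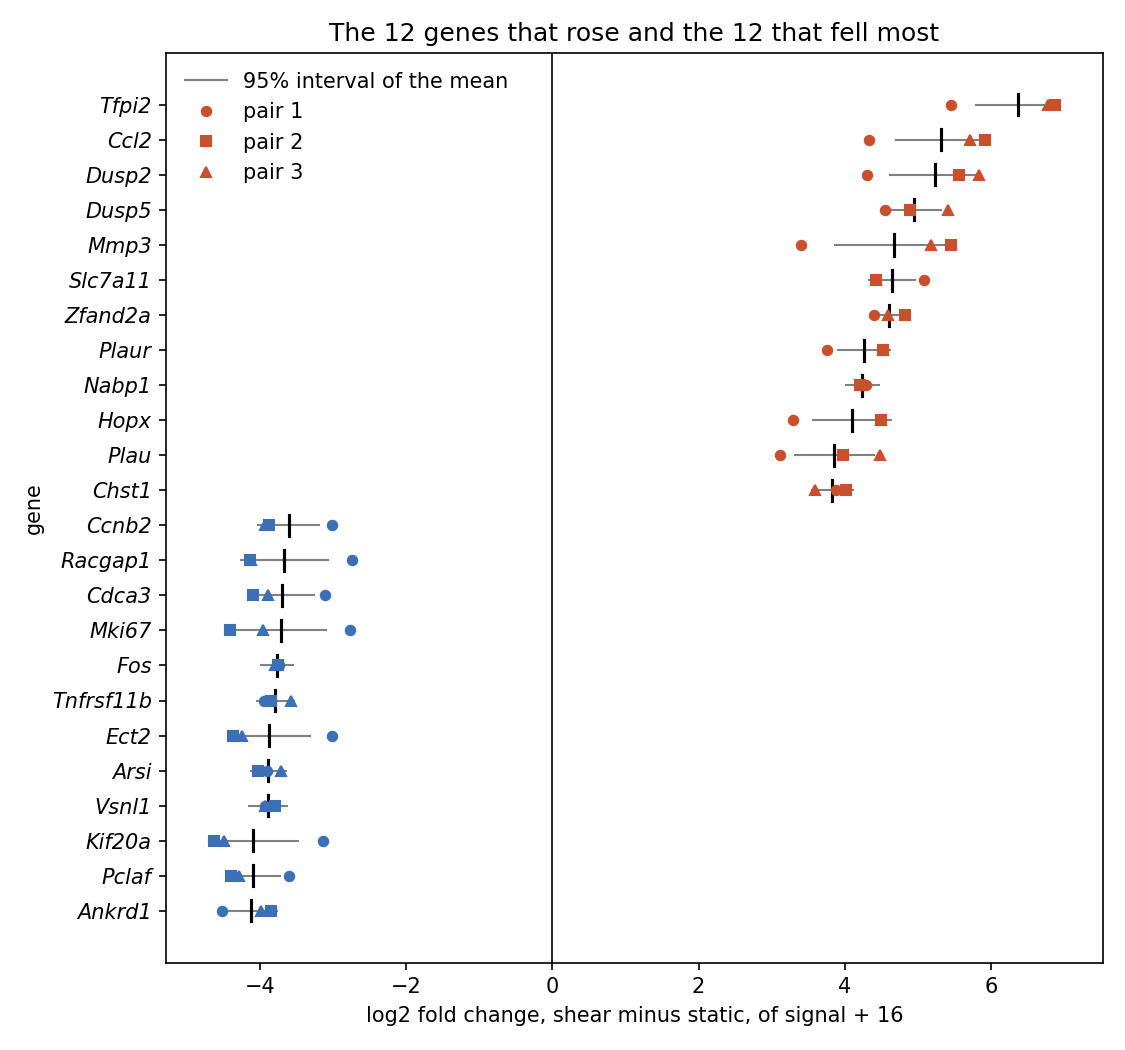
Log2 fold change (shear minus static, of signal + 16) of the 12 genes that rose and the 12 that fell most, with each pair as a symbol, the mean as a bar and its 95% interval as a line. Tfpi2 stands at 6.37 and Ankrd1 at -4.12.

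Coagulation and fibrinolysis genes moved in both directions: 5 rose, 6 fell and 8 did not pass, with the same counts adjusted over the list alone. Besides Tfpi2, Plau and Plaur, the endothelial protein C receptor Procr rose by 2.43 and Serpinb2 by 1.57. Tissue factor itself, F3, fell from 1394 ± 115 to 220 ± 110 (SD, n = 3; -2.67), and the thrombin receptor F2r (-1.34) and Gas6 (-2.39) fell, although 1 of 3 Gas6 probe sets did not pass. As a set, the list did not stand apart from other genes (camera adjusted p = 0.803).

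**Figure D2:**
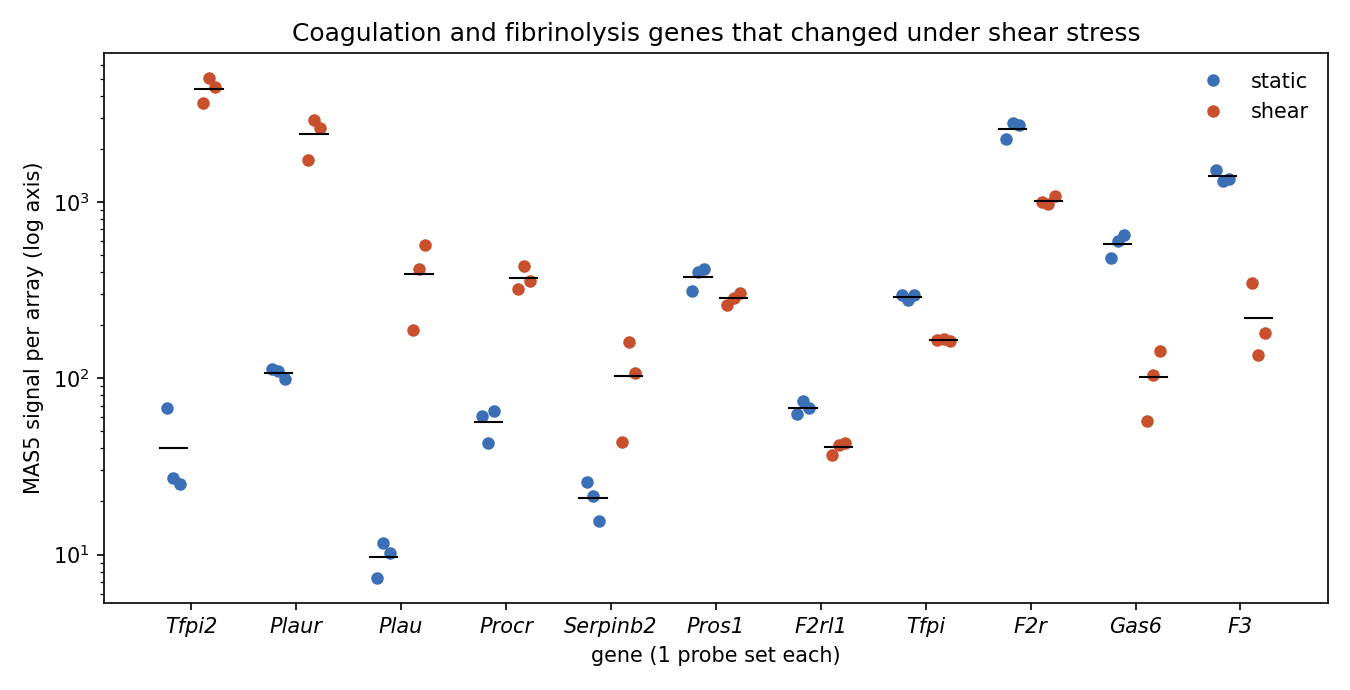
MAS5 signal per array (log axis) of the coagulation and fibrinolysis genes that changed, static arrays in blue and shear arrays in red, with the group mean as a bar. Mean Tfpi2 signal was 40.0 in static and 4396 in sheared cells, and mean F3 signal 1394 and 220.

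Cell cycle genes fell almost without exception. Of 41 tested, 40 fell, 0 rose and Pcna did not pass (0.15, adjusted p = 0.39), and the counts adjusted over the list alone were equal. The list's median was -2.49, and camera gave an adjusted p = 8.9e-16, or adjusted p = 0.51 with an estimated correlation. Thymidine kinase Tk1 fell by 3.51, the ribonucleotide reductase subunit Rrm1 by 2.99, the mitotic kinesin Kif11 by 3.27 and the replication factor Gins1 by 2.37. Without pair 1, Pcna passed as risen (0.40), in a fit with 1 residual degree of freedom.

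Genes of the NRF2 oxidative stress response rose: 20 of 24, with 0 fallen, also when adjusted over the list alone. Their median was 0.94 (camera adjusted p = 5.0e-08; adjusted p = 0.48 with an estimated correlation). Sulfiredoxin Srxn1 rose by 3.46, thioredoxin reductase Txnrd1 by 2.89, Osgin1 by 3.19 and heme oxygenase Hmox1 by 3.75. Heat shock genes had 10 of 17 risen and 3 fallen, or 12 and 3 adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.019; adjusted p = 0.51 with an estimated correlation). Hspb8 (2.84), Bag3 (1.64) and Cryab (0.50) rose, whereas Hspa4 fell (-2.19). The heat shock call was lost after quantile normalization (median 0.20, adjusted p = 0.089), the median was 0.41 after median centring, and 6 members rose without pair 3.

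Contractile genes fell in 14 of 21 cases and rose in 0 (2 after median centring), also adjusted over the list alone, with a median of -0.80 (camera adjusted p = 0.00069; adjusted p = 0.51 with an estimated correlation). Myosin light chain kinase Mylk fell by 2.82, smooth muscle actin Acta2 by 1.10 and leiomodin Lmod1 by 2.01. Tpm1 fell by 1.03 on its brightest probe set, but its 6 probe sets ranged from -2.23 to 1.22 and 2 of them rose. Tagln (0.07) and Myocd (-0.17) did not pass; Tagln passed after median centring (0.22). Targets of YAP and SRF fell in 21 of 33 cases and rose in 7, also adjusted over the list alone (median -0.39, camera adjusted p = 0.019; adjusted p = 0.51 with an estimated correlation). After median centring 16 fell and 8 rose, with a median of -0.24, and 16 fell without pair 2 or without pair 3. Ankrd1, Crim1 (-1.93), Amotl2 (-1.34) and Ccn3 (-1.17) fell, whereas the integrin subunits Itgb3 (1.77) and Itga5 (1.09) rose. Ccn2 did not pass (-0.09), though it passed as fallen after quantile normalization (-0.24) and without pair 1 (-0.17). Beside targets, the list holds regulators such as Yap1, Wwtr1, Tead1 and Lats2.

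Cholesterol synthesis genes fell in 16 of 21 cases and rose in 2, Ggps1 (0.79, with 1 of 3 probe sets not passing) and Tm7sf2 (0.85), with the same counts adjusted over the list alone. The median was -0.81 (camera adjusted p = 0.0058; adjusted p = 0.84 with an estimated correlation). Dhcr7 fell by 2.31, Lss by 1.94, Idi1 by 0.90 and Insig1 by 0.76.

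Hypoxia and glycolysis genes rose in 13 of 26 cases and fell in 3, or 14 and 3 adjusted over the list alone. The median was 0.46 (camera adjusted p = 0.0072; adjusted p = 0.84 with an estimated correlation). With the pair as a random block (adjusted p = 0.055) or robust estimation (adjusted p = 0.073) the call was lost. The glucose transporter Slc2a1 rose by 2.99, Pfkp by 1.87 and Hk1 by 1.47. Car9 (-1.12) and the collagen prolyl hydroxylases P4ha1 (-1.18) and P4ha2 (-0.82) fell, though P4ha2 did not pass as a mean over its probe sets. The median was 0.009 in pair 1 and 0.79 and 0.69 in pairs 2 and 3, and 21 genes rose without pair 1 (median 0.72), whose shear array stood apart. ER stress and amino acid response genes had a median of 0.38 in pair 1 and -0.18 and -0.11 in pairs 2 and 3, a difference that was not tested. Of 32, 11 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.645). Without pair 1, 16 fell, and after quantile normalization 7 rose. Slc7a5 (2.00), Dnajb9 (1.69) and Slc3a2 (1.35) rose and Vldlr fell (-1.39).

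Extracellular matrix genes fell in 18 of 38 cases and rose in 5, or 18 and 6 adjusted over the list alone (camera adjusted p = 0.147). Versican Vcan (-1.87, with 1 of 5 probe sets not passing), Col6a3 (-1.70), Col8a1 (-1.21) and fibrillin Fbn1 (-1.19) fell. Without the block 0 rose, after median centring 12 rose and 15 fell, and without pairs 1 and 3 the risen counts were 10 and 2. Elastin Eln and the collagen Col1a1 had probe sets that differed: the brighter did not pass (-0.05 and -0.12), while the other fell (-2.10 and -1.06). As means over probe sets both passed as fallen (-1.07 for Eln and -0.59 for Col1a1). The brighter Col1a1 probe set also passed as fallen after quantile normalization (-0.28) and without pair 1 (-0.14). Fn1 (0.09) did not pass, though it passed after median centring (0.24) and without pair 1 (0.12). Col1a2 (0.04) did not pass, with a second probe set fallen (-0.47); it passed as fallen after quantile normalization (-0.13) and as a mean over its probe sets (-0.22), and as risen after median centring (0.18). Dcn rose by 0.39 in the paired fit (adjusted p = 0.0010) but did not pass without the block (adjusted p = 0.20). Matrix proteases and inhibitors split into 10 risen and 11 fallen of 27, also adjusted over the list alone (camera adjusted p = 0.909). Mmp3 and Timp3 (1.00) rose, while Reck (-2.10) and Mmp16 (-1.69) fell. Mmp2 had 1 risen probe set (0.60) and 1 fallen (-0.52).

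Among vasoactive mediators, 5 rose and 6 fell of 20, also adjusted over the list alone (camera adjusted p = 0.909). Endothelin Edn1 fell from 312 ± 89.0 to 10.9 ± 2.89 (SD, n = 3; -3.58), and the angiotensin receptor Agtr1a (-3.23) and guanylate cyclase subunit Gucy1a1 (-1.50) fell. Adrenomedullin Adm rose by 2.59 and cyclooxygenase Ptgs2 by 2.88. Growth factors and receptors had 15 risen and 9 fallen of 33, or 15 and 10 adjusted over the list alone (camera adjusted p = 0.645). Tgfb2 (-2.78), Tgfb3 (-2.11), Pdgfra (-2.26) and Pdgfrb (-3.02) fell, whereas Tgfb1 (1.31), Fgfr1 (1.24) and Bmp2 (3.46) rose.

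Flow-responsive and immediate early genes had 12 risen and 9 fallen of 28, also adjusted over the list alone (camera adjusted p = 0.60). Fos and Dusp1 (-2.66) fell and Fosl1 rose (2.89). Klf2 (-0.41, adjusted p = 0.023) and Klf4 (-0.41, adjusted p = 0.013) fell, but neither passed after median centring (-0.26 for both) or without pair 3. Klf2 also did not pass on 2 of its 4 probe sets (the highest at 0.04) or as a mean over them (-0.26, adjusted p = 0.071), nor Klf4 without pair 2 (-0.29, adjusted p = 0.14). Egr1 rose by 0.23 (adjusted p = 0.025) and did not pass without the block (adjusted p = 0.40), with a random block, after quantile normalization, without the intensity trend, or without pair 2 or pair 3. Inflammation genes had 6 risen and 6 fallen of 20, or 7 and 6 adjusted over the list alone, with 13 below the filter (camera adjusted p = 0.645). Ccl2 and Ccl7 (3.62) rose, and Cxcl12 (-2.72) and Tnfaip3 (-0.96) fell. Il6 did not pass (1.20, adjusted p = 0.051), and passed without pair 1 (2.04), without the block or with a random one, after median centring and with a pseudocount of 64.

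Interferon genes had 12 fallen and 3 risen of 23, also adjusted over the list alone (median -0.47, or -0.18 with a pseudocount of 64, camera adjusted p = 0.093). Gbp2 (-2.08), Ifit2 (-2.77), Irf1 (-1.63) and Psmb9 (-1.31) fell. Mx1 (0.58), Oasl (0.42) and B2m (0.49) rose, but Mx1 and Oasl did not pass without pair 2 or without pair 3, nor Oasl without the filter, and a second B2m probe set did not pass (0.25). Apoptosis genes had 12 risen and 8 fallen of 30, or 12 and 9 adjusted over the list alone (camera adjusted p = 0.645), while 4 fell after median centring or without pair 3 and 5 without pair 2. Bid (2.40) and Casp6 (1.09) rose, while the death receptor Fas (-2.05) and Gadd45b (-1.27) fell. Bcl2, with a low signal of 11.5 ± 2.70 against 3.53 ± 1.01 (SD, n = 3), fell by 0.49, a call lost under both scalings and without pair 1 or pair 3. Circadian genes had 7 risen and 3 fallen of 18, also adjusted over the list alone (camera adjusted p = 0.154), with a median of 0.21, or 0.080 without pair 1. Nr1d1 (1.25), Rora (1.31, with a second probe set at 0.33 not passing) and Cry1 (0.99) rose and Dbp fell (-1.81).

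Of 20 endothelial markers 13 lay below the filter, and of the 5 tested 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.909). Flt1 (0.66) did not pass as a mean over its probe sets, nor Egfl7 (-0.40) as such a mean, under either scaling or without pair 3, and Erg (-0.16) and Esam (0.10) did not pass. Leukocyte markers likewise had 13 of 20 below the filter, with 2 risen and 1 fallen of 7, also adjusted over the list alone (camera adjusted p = 0.909). Cd68 (0.70) and Coro1a (0.44) rose and Cd14 fell (-0.68), while Cd3e (-0.26) did not pass. Coro1a did not pass without pair 2 or pair 3. Fibroblast markers had 4 risen and 6 fallen of 16, or 4 and 7 adjusted over the list alone (camera adjusted p = 0.803), while 0 rose without the block and 2 without pair 3. Twist2 (-1.50), Col14a1 (-1.35, with a second probe set at -0.29 not passing), Scara5 (-1.18) and Pdgfra fell.

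**Figure D3:**
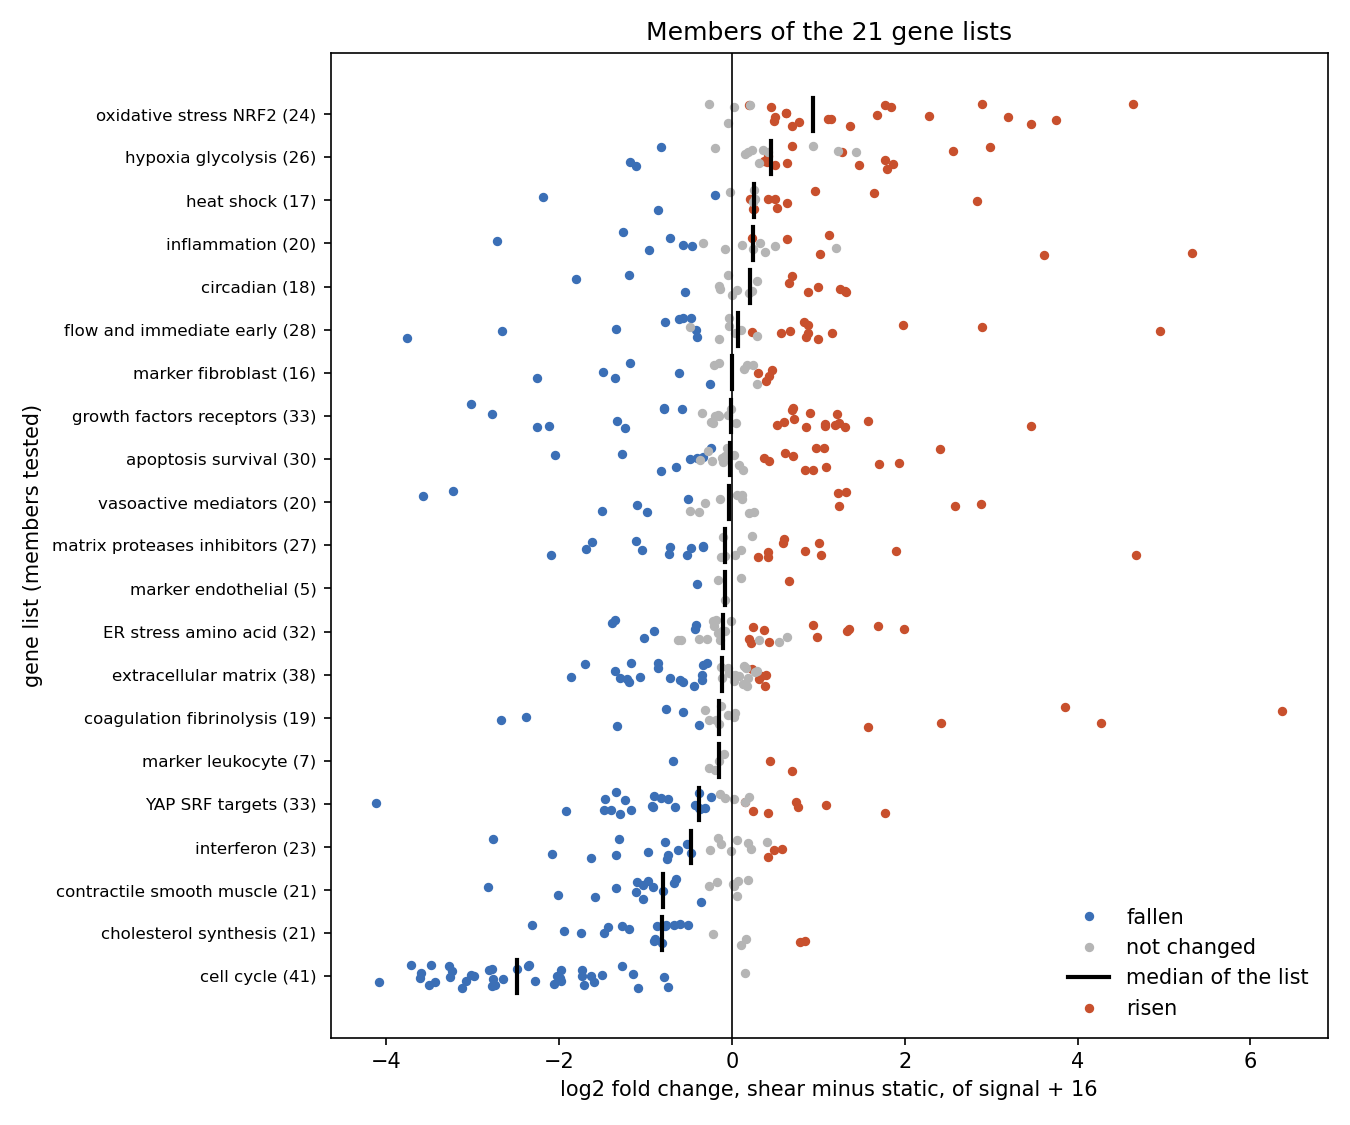
Log2 fold change (shear minus static, of signal + 16) of each tested member of the 21 gene lists, coloured as risen, fallen or not changed, with the median of each list as a bar. Medians ran from -2.49 for cell cycle to 0.94 for oxidative stress.

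RNA quality was compared through control transcripts. The log2 ratio of 3′ to 5′ signal was 0.166 ± 0.0097 in static and 0.156 ± 0.0062 in sheared cells for Gapdh (SD, n = 3; exact permutation p = 0.3). For beta-actin it was 0.255 ± 0.036 and 0.393 ± 0.028 (exact permutation p = 0.1, the smallest possible). Camera called 3 to 7 lists when the 6 arrays were regrouped in other ways, against 7 for the real groups. Fitted with the pair block, those regroupings still hold the shear minus static difference of 1 or more pairs. They therefore cannot show how many lists chance would call. The direction of camera's statistic opposed the median for apoptosis (-0.021), ER stress (-0.099), growth factors (-0.011), proteases (-0.076) and endothelial markers (-0.079), and opposed the mean for coagulation (0.49).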

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

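The tests of scaling and of RNA degradation were chosen after the result was seen, as were the limits that picked out the control probe sets. What the regrouping of arrays should show was set before it was run, with the calls for the real groups already known. The limit for RNA degradation was later changed from the median to every transcript.

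Among 57 control probe sets, outside the main measurement, 4 had all sheared arrays above all static ones, at least 2-fold higher means and a sheared mean above 50. Chance puts all 3 sheared arrays above all 3 static ones for 5% of probe sets, before the limits on fold and signal, and 3 of the 4 are parts of 1 transcript, hexokinase. The 5S ribosomal RNA control was 95.5 in static and 320.97 in sheared cells. The hexokinase controls were 85.7 and 228.27 at the 3′ end, 62.3 and 138.07 in the middle, and 49.4 and 132.87 at the 5′ end. Hexokinase genes rose in the main measurement too, Hk1 from 256.7 to 741.7 and Hk2 from 46.8 to 380.9.

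The breadth of the response, 11471 of 21729 probe sets, could come from array scaling, RNA degradation, shear stress or other differences between the chamber and static cultures. Those other differences cannot be told apart from shear stress in this design. After quantile normalization 90.48% of the called probe sets were called with the same sign, which argues against scaling as the whole cause. RNA degradation stays open: the 3′ to 5′ log2 ratio differed by -0.010 for Gapdh, by 0.0185 (the median) for hexokinase, with an SD of 0.297 in sheared cells, and by 0.139 for beta-actin, whose sheared ratios all lay above the static ones (exact permutation p = 0.1, the smallest possible), as did the 5S ribosomal RNA signals. Regrouping the arrays gave as many calls in 1 of 10 splits, the real one. In limma the highest other split had 0 calls (25 to 266 at an unadjusted p under 0.05), also in the 3 others that part every pair. These splits are no test of chance, because with the pair block they still hold shear differences of the parted pairs. Some are also the same contrast up to sign, and 10 splits are too few for a share under 0.05.

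Camera called at least 7 lists in 3 of the 10 splits, the real one included, and the highest other split had 7. With the pair block, the others with 7 were 1 contrast up to sign, the shear minus static difference of pair 2. They repeat the shear response and are no test of chance. The 10 splits are also too few for a share under 0.05.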

How the results depend on the processing

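Only the pseudocount of 1 was chosen after seeing the data. Tfpi2 kept its direction and its call under every alternative run, between 6.12 and 6.83 when a pair was left out. Without the replicate block 11430 probe sets changed, and 11049 of the 11471 calls were kept. Leaving out a pair gave 8389 to 13024, from fits with 1 residual degree of freedom. Counts of at least 2-fold changes were 680 risen and 953 fallen at a pseudocount of 64, and 2039 and 3198 at 1, since the added constant shrinks changes of dim probe sets. For list medians, with causes not tested: the extracellular matrix list became called with a random block (-0.12), robust estimation (-0.12), quantile normalization (-0.28), the mean over probe sets (-0.33), and without replicate 1 (-0.24) or 3 (-0.13), but not without replicate 2 (-0.082) or after median centring, where the median turned positive (0.031). Interferon became called with the 50% filter (-0.75), fry (-0.47) and without replicate 3 (-0.47), but not without replicate 1 (-0.42) or 2 (-0.36). Hypoxia and glycolysis lost its call with a random block, robust estimation, an estimated correlation and fry (0.46 in each). Heat shock lost it after quantile normalization (0.20). Camera with an estimated correlation ended every list call: cell cycle (-2.49), cholesterol (-0.81), contractile (-0.80), heat shock (0.26), NRF2 (0.94) and YAP and SRF (-0.39). The correlation itself was -0.017 for NRF2 and -0.018 for heat shock, below the preset 0.01, so it did not end those calls. For the others it ran from 0.023 (YAP and SRF) to 0.535 (cholesterol). With few residual degrees of freedom, their lost calls cannot be put down to correlation alone. Under fry, which asks another question, cholesterol was not called (-0.81), and circadian (0.21, but 0.080 without replicate 1) and fibroblast markers (-0.0053) were. Leaving out the block changed no list call.

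Of 1395 values of the 100 genes' probe sets chosen by the rule, 1388 kept direction and side of the threshold, 7 lost the call and 0 reversed. The rule mostly took the largest passing changes or the smallest p, so this stability was largely fixed by the selection. Some of the 94 probe sets looked at after results were seen were picked because their calls differed between settings. The sets therefore cannot be compared for stability. Of the 1311 values of the 94, 37 lost a call, 23 gained one and 3 reversed. Those were Col1a2 after quantile normalization (-0.13) and as a mean over probe sets (-0.22), and Ddit3 without replicate 1 (-0.38, with 1.06 at the other end of the range when a pair was left out); neither gene passed in the fit reported, and the cause was not tested. Signal over background is unknown without detection calls, which limits what dim probe sets show.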

Other observations

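All lists in the first paragraph and the tests of scaling and cell cycle phase were chosen after results were seen. The metal test was set once the NRF2 and heat shock genes were known to have risen, but before it was run. Its intervals under other scalings were added later.

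Genes of ribosome biogenesis rose in 32 of 40 cases and fell in 0 (median 0.75; camera adjusted p = 2.1e-09 over a family of 12 lists; adjusted p = 0.39 with an estimated correlation). Utp15 (1.51), Rrp12 (1.27) and Ncl (0.76) were among them. Proteasome genes rose in 24 of 36 cases, for example Psmb3 (1.35) and Psmd8 (1.20), and the 3 that fell were the immunoproteasome subunits Psmb8 (-0.97), Psmb9 (-1.31) and Psmb10 (-0.75) (adjusted p = 4.2e-05; adjusted p = 0.39 with an estimated correlation). Vacuolar ATPase genes rose in 14 of 19 cases and fell in 1 (adjusted p = 0.00033), and chaperonin genes rose in 8 of 8 (adjusted p = 0.0017; adjusted p = 0.39 with an estimated correlation for both lists). Autophagy genes were mixed and tested as higher (median 0.23, or 0.37 after median centring; adjusted p = 0.026; adjusted p = 0.39 with an estimated correlation). Of 27, 12 rose, such as Gabarapl1 (2.02), Sqstm1 (1.77, with 1 of 3 probe sets not passing, at -0.06) and Wipi2 (1.49), and 6 fell, such as Atg3 (-0.91), Wipi1 (-0.89) and Becn1 (-0.72). Oxidative phosphorylation genes fell in 41 of 70 cases and rose in 5 (median -0.29, or -0.14 after median centring; adjusted p = 0.00097; adjusted p = 0.48 with an estimated correlation). Histone genes fell in 7 of 12 cases (adjusted p = 0.0076; adjusted p = 0.39 with an estimated correlation). Cytosolic ribosomal proteins rose in 18 of 41 cases and fell in 1 (adjusted p = 0.0010; adjusted p = 0.39 with an estimated correlation), but their median of 0.13 turned to -0.029 after quantile normalization and was 0.28 after median centring. Dual-specificity phosphatases (all Dusp genes tested, not MAP kinase phosphatases alone; adjusted p = 0.44), cytosolic tRNA synthetases (0.54), potassium channels (0.25) and mitochondrial ribosomal proteins (0.40) did not stand apart.

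In 5 genes picked after their values were seen, the change in pair 1 lay apart from those in pairs 2 and 3. The change of Slc16a3 was -0.93 in pair 1 and 2.76 and 2.48 in pairs 2 and 3. For Bnip3 the changes were 0.21, 2.59 and 2.29, and for Pdk1 0.13, 2.58 and 2.60. Ddit3 went the other way, at 2.40, -0.29 and -0.48, as did Asns at 1.10, -0.77 and -0.88. In the limma fit of all pairs Slc16a3 (adjusted p = 0.084), Ddit3 (adjusted p = 0.38) and Asns (adjusted p = 0.68) did not pass. Without pair 1, Slc16a3 passed as risen (2.62) and Ddit3 (-0.38) and Asns (-0.82) as fallen. These genes were picked with their pair values in view. Calls from pairs 2 and 3 alone were therefore largely fixed by that choice and are no separate evidence. A second Pdk1 probe set did not pass (-0.35), nor did the mean over both (0.71, adjusted p = 0.11), and with robust estimation neither Pdk1 (adjusted p = 0.10) nor Bnip3 (adjusted p = 0.092) passed. The difference between pairs was not tested.

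The fall of the cell cycle genes could come from array scaling, a shift between phases, or less cycling under shear stress or other conditions of the chamber. Under the scaling that brought it nearest to 0, the list's median was -2.34, which argues against scaling. The G1/S genes had a median of -1.98 with 15 of 16 fallen and the G2/M genes -2.92 with 24 of 24 fallen, so neither set rose. Both sets were drawn from this same list, of which 40 of 41 genes were already known to have fallen. Opposite signs could not have come out, so this is no separate test of a shift between phases. A lower share of cycling cells is a hypothesis that stays open, and no cell counts were analysed here.

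The rise of NRF2 and heat shock genes might come from array scaling, metal exposure in the flow circuit or shear stress. The NRF2 median was 0.87 under the scaling that lowered it most, which argues against scaling for that list. The heat shock median was 0.26, and 0.20 after quantile normalization, which ended the call with 10 risen and 3 fallen as before, and 0.41 with 13 risen after median centring. Metal exposure stays open. The metallothioneins Mt2A (2.46) and Mt1 (0.68) rose, Mt1 near the floor (6.43 ± 4.92 static, 19.6 ± 4.94 sheared, SD, n = 3). The zinc importer Slc39a10 fell (-1.22). The dim zinc exporter Slc30a1 was set, before the metal test was run, to decide by lying below 0.5. Its value was 0.22 (95% interval -0.05 to 0.49) but 0.37 after quantile normalization (0.10 to 0.64), so that bound was too close to its spread. Other differences between the chamber and static dishes, such as medium volume, were not tested and stay open.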
